A study of Danio rerio with 48 samples.

How the data were processed

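RNA sequencing was carried out on whole brains of adult zebrafish of the AB laboratory line, in 48 libraries from 3 generations. The submitters extracted total RNA from dissected, frozen brains with a TriPrep kit and sequenced it as read pairs on a BGISEQ-500, per the labels' protocols. Reads were processed with STAR 2.7, HTSeq 0.11.2 and DESeq2 1.24.0 on the build GRCz11 (danRer11), per the submitters' processing notes. The strand setting of the counting and the annotation release are not given in the sources used here, so reads of a gene and of an overlapping or antisense neighbour cannot be told apart.

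Each deposited file holds the raw read counts of 1 library for the same 32520 Ensembl genes in the same order, with 5 summary lines that name no gene. Those lines stayed out of library sizes and tests. Read pairs assigned to genes made up 31.4 to 36.6% of the total of genes and summary lines, pairs over no annotated feature 60.3 to 65.4%, pairs that did not map uniquely 2.40 to 3.12%, and ambiguous pairs 0.31 to 0.60%. Counts in genes ranged from 4802827 to 10032850 per library. A control group with under 3 counts was given a floor of 3 counts over the group, which covers counting error only, as the reads carry no molecular identifiers.

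Gene symbols came from the reference table of gene names, which named 29201 IDs and left 3319 without a symbol. Many symbols follow human spelling in capitals although every gene is a zebrafish gene, and 6136 IDs share their symbol with another ID, in which case the Ensembl ID stands beside the symbol. Genes with near-identical or neighbouring copies, such as cry3a and cry3b, the parvalbumin, globin and vitellogenin genes and the si:ch211-209l18 genes, are uncertain. Pairs that did not map uniquely or were ambiguous stand in the summary lines, so reads shared by copies may be missing from these genes. The reference gene table is of the assembly GRCz12tu, another build than the authors', so it served only for which genes neighbour each other and no coordinates are given.

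Groups followed generation, sex and the source code of each sample, with 4 libraries in each of 12 groups. The code PH was read as the permethrin lineage and SCA as its control, a reading that the labels do not spell out. Libraries are named by group and the number in their label. Nothing in the labels says that libraries of a group came from separate tanks or parents, so p-values measure the spread between these fish. Replicates were compared first, and the lowest chi-square per degree of freedom between 2 of a group was 4.8, so none was a duplicate.

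For each generation, edgeR 4.0.16 in R 4.3.3 fitted 4 group means to the 16 libraries after filtering with filterByExpr and TMM normalization, with robust quasi-likelihood dispersions (glmQLFit and glmQLFTest). This left 18081 genes in F0, 18094 in F1 and 17505 in F2, with a biological coefficient of variation of 23.3, 22.6 and 23.5%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Contrasts were the permethrin lineage against control in each sex, the mean of both sexes, the difference between the sexes, and females against males. A joint test on all 48 libraries and 19062 genes asked, within each sex, whether the contrast differed between generations. Standard errors of log2 fold changes were taken from the F statistic. Levels are CPM, counts scaled by the TMM-adjusted library sizes of each generation's fit, given as mean ± SD. Levels of different generations thus rest on separate scaling, while tests of explanations used TMM factors over all 48 libraries.

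Fold changes of 9 pairs of contrasts were correlated across genes, with two-sided exact permutation p-values from 4900 assignments of the arm labels and no library shared between the contrasts of a pair. Gene lists, 51 in number, held 2255 listed members, of which 2106 (93.4%) matched an ID. The 50 lists with at least 5 tested genes entered camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 in each of 6 contrasts. The 300 tests were adjusted together, with camera at an estimated correlation and fry beside them. No list passed with an estimated correlation or by fry in any of the 6 contrasts. Over both sexes, adjusted apart, fry passed 1 list in F0, 2 in F1 and 0 in F2, and none passed with an estimated correlation.

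The design, lists, alternatives and rule for named genes were fixed before the data were examined. For each sex and generation, the rule took called genes with all 4 PH libraries on one side of all 4 SCA libraries, a mean CPM of at least 1 and a proper symbol, and kept the 8 with the largest fold in each direction. Up to 10 called list members by smallest p were added. Where fewer than 6 genes were called, the 3 of smallest p in each direction were taken. For the sexes, the rule took the 4 genes of largest fold in each direction called in all 3 generations. Genes of the mean over both sexes were chosen by the same rule after values were seen, as were those of the generation tests.

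Alternatives were RLE size factors, DESeq2 1.42.0, limma voom with sample quality weights, no filter on low counts or a mean CPM of at least 1, a fit on the 8 libraries of the contrast or on all 48, 1 surrogate variable (sva 3.50.0), the lane named in the file as a covariate in F2, and each library left out in turn. Fits without libraries that stood apart, and with a score of the clock genes as a covariate, were chosen after seeing the data.

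The tests were tested on simulated counts with known changes of 1.5, 2 and 4 times. In the females, the share recovered was 25.4, 47.8 and 83.3% for F0, 16.4, 59.7 and 84.8% for F1, and 13.4, 35.8 and 81.8% for F2. In the males it was 25.4, 46.3 and 81.8% for F0, 13.4, 47.8 and 84.8% for F1, and 17.9, 53.7 and 92.4% for F2. For the mean of both sexes it was 52.2, 74.6 and 95.5% for F0, 35.8, 73.1 and 93.9% for F1, and 32.8, 71.6 and 97.0% for F2. False calls made up 2.6 to 9.2% of calls. A simulated list of 40 genes raised 1.3-fold was called in 10 of 10 runs at the preset correlation and in 10 of 10 at an estimated one, and 2 and 0 of 500 unchanged lists were called. The simulated genes varied independently of each other, so these list rates do not carry over to real lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.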

Results

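Brains of adult zebrafish were profiled in founders (F0) that had met permethrin at 10 µg/L early in life, and in F1 and F2 descendants that were not exposed. Permethrin is a pyrethroid insecticide that holds voltage-gated sodium channels open. Each generation held 4 libraries per sex from the permethrin lineage and 4 from control fish. Counts in genes ranged per library from 7655597 to 8072588 in F0, from 4802827 (F1_F_PH 1) to 10032850 in F1 and from 7381621 to 7680352 in F2. The comparisons asked whether brain transcripts differed in the exposed fish and whether differences appeared in offspring.

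In exposed F0 females, the genes of smallest p among those with higher means were ENTPD4, a nucleoside diphosphatase of the Golgi and lysosomes, PER2, a light-responsive clock gene, and cirbpb, a cold-inducible RNA-binding protein. None of them passed the test. ENTPD4 lay at 55.8 ± 5.72 CPM against 37.0 ± 1.5 in controls (SD, n = 4 each), a log2 fold change of 0.59 ± 0.09 (SE, edgeR adjusted p = 0.0927). PER2 had a log2 fold change of 0.80 ± 0.16 and cirbpb of 0.43 ± 0.09. Among genes with lower means, cyp2ad3, a cytochrome P450, had a log2 fold change of -0.90 ± 0.17, akt1s1, a brake on mTOR signalling, -0.33 ± 0.06, and IQCH -4.27 ± 0.92. Of 45 clock genes tested, 0 were called over all genes and 2 were higher when adjusted over the list alone.

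Of 50 lists in F0 females, 16 passed camera, 4 upward and 12 downward. The photoreceptor and eye list had a median log2 fold change of -1.61 over 41 genes (camera adjusted p = 7.78e-11), with 37 below 0 and 0 called. Its adjusted p was 0.803 with an estimated correlation and 3.62e-06 without F0_F_SCA 18, in a range of 2.89e-21 to 0.803 over all alternatives. In that control female, which stood apart from the other 3, the list median lay 2.15 above the generation mean (log2), and the lens gene cryba1l2, chosen after values were seen, was at 934 CPM against 1.1 to 3.91 in the other 7 females. GNAT2, the cone transducin, had a log2 fold change of -2.38 ± 0.85. The microglia and macrophage list had a median of -0.27 over 27 genes (camera adjusted p = 4.3e-05), with an adjusted p of 0.803 with an estimated correlation. Voltage-gated calcium channel genes had a median of 0.17 over 31 genes (camera adjusted p = 0.000657), with an adjusted p of 0.803 with an estimated correlation.

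In exposed F0 males, prss56, a serine protease, had a log2 fold change of 2.21 ± 0.36 (edgeR adjusted p = 0.24) and SOCS3 (ENSDARG00000025428), a feedback inhibitor of cytokine signalling, of 1.68 ± 0.36. The keratin krt8 stood at 62.2 ± 5.88 CPM against 94.0 ± 9.41 (SD, n = 4 each), grhl2a, an epithelial transcription factor, had a log2 fold change of -1.38 ± 0.27 and the amine oxidase AOC3 of -0.81 ± 0.17. None passed. The cholesterol and lipid synthesis list had a median of -0.28 over 41 genes (camera adjusted p = 1.63e-08), with 31 below 0. With an estimated correlation its adjusted p was 0.684. None of its members was called over all genes, and 10 were lower when adjusted over the list alone, among them SC5D, a late enzyme of sterol synthesis, at -1.10 ± 0.23, and SQLE (ENSDARG00000079946), squalene epoxidase, at -1.41 ± 0.41. Cytosolic ribosomal protein genes had a median of 0.14 over 75 genes (camera adjusted p = 2.93e-08), with an adjusted p of 0.835 with an estimated correlation and of 0.26 without F0_M_PH 12. Skeletal muscle genes had a median of -0.46 over 33 genes (camera adjusted p = 0.000991; adjusted p = 0.834 with an estimated correlation), and 8 were lower when adjusted over the list alone. Without 3 libraries that stood apart (F0_F_SCA 18, F0_M_PH 12 and F0_M_SCA 6) the muscle list's adjusted p was 0.0808, and without F0_M_SCA 6 alone 0.621, in a range of 1.16e-06 to 0.834 over all alternatives.

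Averaged over both sexes of F0, krt8 at -0.46 ± 0.07, cyp2ad3 at -0.73 ± 0.12 and the cryptochrome cry3a at 0.50 ± 0.08 (log2 fold change ± SE, n = 8 each) came closest to the threshold (edgeR adjusted p = 0.146 for each). At an adjusted p of 0.05, edgeR called 0 genes in F0 females, 0 in F0 males, 0 over both sexes and 0 for the difference between sexes. At an unadjusted p under 0.05 there were 921, 1096, 1348 and 579 genes, against about 904 given by chance. DESeq2 called 18, 10, 57 and 0 genes, and limma voom 1, 0, 0 and 0. Fitting all 48 libraries called 32 genes in F0 females. In F0 males, PH libraries ran on lane L4 and SCA libraries on L2, so lane and group cannot be told apart there.

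In F1 females of the permethrin lineage, 12 genes fell and 0 rose. KLF9, a transcription factor induced by glucocorticoids and thyroid hormone, stood at 6.64 ± 3.84 CPM against 80.6 ± 31.6 in controls (SD, n = 4 each). This was a log2 fold change of -3.54 ± 0.55 (SE, edgeR adjusted p = 0.0325). F0 control fish of both sexes held 4.61 to 40.1 CPM of KLF9, on TMM factors over all 48 libraries. The PH mean of F1 females lay within that range and the control mean above it. NOCT (ENSDARG00000077726), a rhythmically expressed phosphatase, fell by 1.79 ± 0.29 on the log2 scale, and STK40, a kinase-like protein, by 1.37 ± 0.23. Falls in a narrower range, from -1.29 to -0.78, were found in SLC25A43, SERTAD2, eif4a1a, ERF (ENSDARG00000063417), MIDN, SOX11 (ENSDARG00000095743) and MFSD2A (ENSDARG00000035909). ERF is an ETS-family repressor, eif4a1a a helicase of translation initiation, SOX11 a factor of neuronal development and MFSD2A a lipid transporter of brain vessels. Outside the rule for naming, and chosen after values were seen, SLC3A2 and si:dkey-201c13.2 also fell.

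Immediate-early genes, induced by neuronal activity, had a median log2 fold change of -0.45 over 47 genes in F1 females (camera adjusted p = 3.73e-08; adjusted p = 0.803 with an estimated correlation). None was called over all genes, while 10 were lower and 1 higher when adjusted over the list alone. Of these, csrnp1a had a log2 fold change of -1.90 ± 0.40, EGR3 of -0.93 ± 0.22 and DUSP1 of -1.15 ± 0.29. Circadian clock genes had a median of -0.40 over 45 genes (camera adjusted p = 0.000171; adjusted p = 0.803 with an estimated correlation), with 0 called over all genes, 3 higher and 10 lower over the list alone. In the stress axis and glucocorticoid list (29 genes, median -0.05, camera adjusted p = 0.00188; adjusted p = 0.803 with an estimated correlation), KLF9 was called and 6 members were lower over the list alone. FKBP5, a glucocorticoid-induced co-chaperone, stood at -2.96 ± 0.91 and HSD11B2, which inactivates cortisol, at -1.45 ± 0.35, neither called over all genes. The photoreceptor and eye list had a median of -1.12 over 38 genes (camera adjusted p = 5.61e-07, and 0.803 with an estimated correlation). Against the generation mean, its library medians overlapped, at -0.405 to 0.389 in PH females and -0.19 to 1.032 in control females. The count of 12 moved to 1 without F1_F_PH 1, the shallowest library, and to 29 without F1_F_SCA 4, and none of the 10 genes named by rule was called in every fit that left out a library.

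In F1 males of the permethrin lineage, 14 genes rose and 5 fell. The cryptochromes cry3b and cry3a, repressors of the clock, rose: cry3b went from 37.6 ± 10.8 to 114 ± 26.8 CPM (SD, n = 4 each), a log2 fold change of 1.6 ± 0.24 (SE, edgeR adjusted p = 0.0273), and cry3a rose by 1.17 ± 0.19. The clock activator BMAL1 (ENSDARG00000006791) rose by 1.06 ± 0.19 and the rhythmic repressor NFIL3 by 1.03 ± 0.16. NEIL1, a DNA repair glycosylase, rose by 1.37 ± 0.23, and the transporters ABCA7 and ABCC1 by 1.2 ± 0.20 and 0.66 ± 0.11. PRDM12 and lonrf4 rose by 0.82 ± 0.14 and 0.69 ± 0.12. Falls were found in the claudin cldn3c (-3.16 ± 0.57), the glutamine transporter SLC38A3 (ENSDARG00000091061, -1.79 ± 0.28), the splicing factor smu1b (-1.15 ± 0.21), DTX3 (-0.95 ± 0.16) and RIMBP2 (ENSDARG00000104101, -0.91 ± 0.13), a protein of presynaptic release sites.

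Of the 45 clock genes in F1 males, 4 were called higher and 0 lower over all genes, and 10 were higher and 18 lower when adjusted over the list alone. The list median of -0.27 did not pass (camera adjusted p = 0.199). Genes of heat shock and the unfolded protein response had a median of 0.19 over 50 genes (camera adjusted p = 3.25e-07; adjusted p = 0.345 with an estimated correlation). None was called over all genes and 8 were higher and 1 lower over the list alone. HSPA5, the chaperone BiP, stood at 0.50 ± 0.10 and HSPH1 at 0.68 ± 0.13. Markers of telencephalon (median 0.48, 35 genes, camera adjusted p = 3.6e-06, adjusted p = 0.684 with an estimated correlation) and of hypothalamus and preoptic area (median 0.41, 37 genes, 4.7e-07, adjusted p = 0.803 with an estimated correlation) had medians above 0. Cerebellum markers had a median below 0 (-0.36, 33 genes, camera adjusted p = 0.00109, adjusted p = 0.803 with an estimated correlation). Hypothalamic neuropeptide genes, with 29 of 37 above 0, had a median of 0.30 (camera adjusted p = 4.3e-05; adjusted p = 0.803 with an estimated correlation). The count of 19 moved to 0 without F1_M_PH 4 or in a fit on the 8 male libraries, to 1 with limma voom, and to 46 without F1_M_PH 8.

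Averaged over both sexes of F1, 123 genes were called, 52 higher and 71 lower, and all 8 PH lay apart from all 8 SCA libraries in 38 of 18094 tested genes (0.21%, against 0.02% by chance), 26 of them called. These genes were chosen by the same rule after values were seen. KLF9 fell by 3.26 ± 0.42 on the log2 scale (edgeR adjusted p = 0.00333). In the clock list, 4 genes were called higher (cry3b, cry3a, BMAL1 (ENSDARG00000006791) and NFIL3) and 3 lower (dbpb, dbpa and tefb, PAR-domain output factors), with 11 and 22 over the list alone. The log2 fold change was 1.34 ± 0.17 for cry3b and -0.91 ± 0.17 for dbpb. Other rises were SDHA, a subunit of mitochondrial complex II (0.46 ± 0.06), uqcc3 (0.57 ± 0.09), which serves complex III assembly, and HCCS (ENSDARG00000028131, 0.93 ± 0.13), which attaches haem to cytochrome c. Falls included the histone demethylase KDM6B (-0.79 ± 0.13), the phosphodiesterase pde4ca (-0.88 ± 0.15), zfand5a (-0.86 ± 0.13) and ITM2C (ENSDARG00000039650, -1.33 ± 0.28). For the difference between the sexes, edgeR called 0 genes, with 924 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma voom. With a score of the clock genes as a covariate, chosen after seeing the data, 0 of the 123 genes were called, while their fold changes kept a median of 70% of their size and standard errors grew 1.52 times, as the score also differed between arms. Without F1_F_PH 2 the count was 60.

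**Figure D1:**
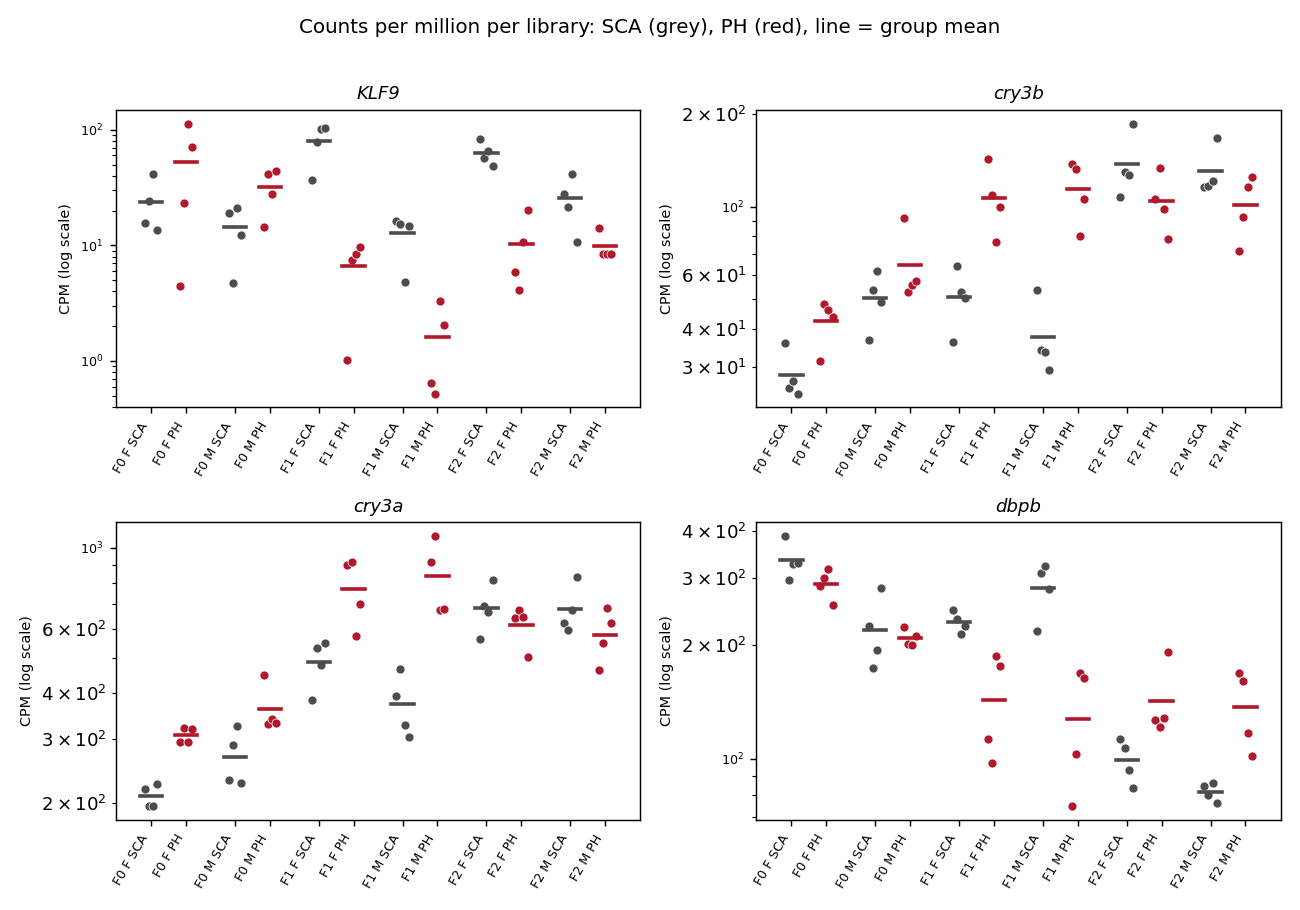
CPM (log axis) of KLF9, cry3b, cry3a and dbpb in each of the 48 libraries, by generation, sex and arm; points are libraries, lines are group means, SCA is grey and PH red. In F1 females KLF9 was at 6.64 ± 3.84 CPM in the permethrin lineage against 80.6 ± 31.6 in controls (mean ± SD).

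In F2 females of the permethrin lineage, 13 genes rose and 11 fell. KLF9 was again lower, at 10.2 ± 7.15 CPM against 63.6 ± 15 in controls (SD, n = 4 each). This was a log2 fold change of -2.64 ± 0.43 (SE, edgeR adjusted p = 0.0268). As in F1, the PH mean lay within the 4.61 to 40.1 CPM of F0 control fish and the control mean above it. Whether the lineage fell or the controls stood high was thus not settled. Also lower than in controls were usp2b, a deubiquitinase (-2.11 ± 0.39), csrnp1a (-1.69 ± 0.27), pik3r3a (-1.21 ± 0.22) and IRS2 (ENSDARG00000075282, -0.81 ± 0.10), both in insulin signalling, ERF (ENSDARG00000063417, -1.2 ± 0.20), the cadherin CDH24 (-1.17 ± 0.18), the clock-linked repressor nfil3-5 (-1.07 ± 0.13) and the kinase PDK2 (ENSDARG00000020876, -0.72 ± 0.10), which restrains pyruvate dehydrogenase. Rises were plxdc2a (3.92 ± 0.69), arhgef28b (3.08 ± 0.48), bloc1s3 (2.0 ± 0.26), a subunit of the complex for lysosome-related organelles, and the galectin lgals9l1 (1.16 ± 0.20). For plxdc2a, F0 control fish ran from 0 to 2.85 CPM. Of 16 control fish of F0 and F1, 7 lay on the permethrin side of the midpoint between the F2 arms. The PH females held 3.58 to 7.31 CPM of arhgef28b and F2 control females 0 to 0.965, but control females reached 8.44 in F0 and 12.7 in F1. For bloc1s3 the PH females held 6.88 to 11.7 CPM, above the 4.52 and 5.14 reached by control females of F0 and F1. Control males reached 6.44 in F1, within the 5.26 to 9.11 of F2 PH males. PH females of earlier generations held 1.35 to 7.43 CPM in F0 and 1.3 to 5.11 in F1. The brain fatty acid binding protein FABP7 (ENSDARG00000007697), a radial glia marker, rose by 0.44 ± 0.07, and ZNF395 (ENSDARG00000024195), ovch1, AQP11 and mid1ip1l by 0.48 to 0.86.

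Several lists passed camera in F2 females, and none with an estimated correlation. Cytosolic ribosomal protein genes were above 0 in 75 of 75, with a median of 0.26 (camera adjusted p = 7.01e-11; adjusted p = 0.835 with an estimated correlation) and 0 called. Against the generation mean, the list medians were -0.486 and -0.331 in controls F2_F_SCA 4 and 8, but 0.105 and 0.203 in F2_F_SCA 6 and 9, next to 0.11 to 0.262 in the PH females. Voltage-gated potassium channel genes had a median of -0.60 over 35 genes (camera adjusted p = 0.00188; adjusted p = 0.834 with an estimated correlation), calcium channel genes -0.48 over 31 (0.00303; adjusted p = 0.834 with an estimated correlation) and sodium channel genes -0.59 over 10 (0.0151; adjusted p = 0.827 with an estimated correlation, 0.0725 without F2_F_PH 5 and 0.0571 without F2_F_SCA 8). KCNQ3, a channel of the M-current, stood at -1.39 ± 0.49 and the calcium channel subunit CACNA1E at -0.68 ± 0.21, neither called. Erythrocyte genes had a median of 0.67 over 13 (0.00153; adjusted p = 0.803 with an estimated correlation), with 5 higher over the list alone. In the stress axis list (28 genes, median -0.08, camera adjusted p = 0.0367; adjusted p = 0.803 with an estimated correlation), KLF9 and PDK2 were called lower and 1 was higher and 4 lower over the list alone; the list's adjusted p was 0.0578 without F2_F_PH 3, 0.13 without F2_F_PH 4 and 0.0991 without F2_F_SCA 9. Of 45 clock genes, 1 was called lower, and 11 were higher and 14 lower over the list alone, with no shift of the list (camera adjusted p = 0.279). Skeletal muscle genes had a median of -1.02 over 36 genes (camera adjusted p = 0.00112; adjusted p = 0.835 with an estimated correlation), with 14 lower over the list alone, but in the control female F2_F_SCA 8 the list median lay 1.35 above the generation mean (log2). Without F2_F_SCA 8 and F2_M_PH 11 the muscle list's adjusted p was 0.382, and without F2_F_SCA 8 alone 0.417, in a range of 5.13e-08 to 0.835 over all alternatives. The PH females 3 and 4 ran on lane L2 and the other F2 libraries on L3. With lane as a covariate, or without those 2 libraries, 0 genes were called. No other F2 library ran on L2, so both fits take the PH female level from F2_F_PH 5 and 16 alone. They are not separate checks, and an effect of lane cannot be told apart from the smaller group. Leaving out F2_F_PH 3 left 3 calls, leaving out F2_F_SCA 9 gave 1251, and 3 of the 18 named genes were called in every fit that left out a library.

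In F2 males of the permethrin lineage, 3 genes were called higher than in controls and 0 lower. The transcript si:ch211-209l18.4 had 0 counts in all 4 controls and 37.7 ± 15.9 CPM in the permethrin lineage (SD, n = 4), at least 381-fold higher against a floor of 3 counts over the control group (edgeR adjusted p = 1.45e-05). Its neighbour si:ch211-209l18.2, with 1 count over the 4 controls, was at least 35.6-fold higher against the same floor, and si:ch211-202m22.1 was higher by 4.66 ± 0.61 on the log2 scale. Both si:ch211-209l18 transcripts also differed between the sexes in their change (edgeR adjusted p = 0.000441 and 0.0251 for the difference). In F2 control females si:ch211-209l18.4 stood at 28.0 to 29.4 CPM, but it ranged from 0.119 to 29.3 CPM in F0 and 0 to 65.3 in F1 control females, and from 0 to 68.7 in F0 and 0 to 28.3 in F1 control males. Males of the permethrin lineage stood at 32 to 62.9 CPM in F0, 0.487 to 59 in F1 and 26.1 to 61.1 in F2. The F2 difference thus came from control males without counts, not from a rise in the lineage over F0. Across all 48 libraries, si:ch211-209l18.4 lay at most at 0.487 CPM, at 21.7 to 33.8 or at 45.6 to 68.7. In the libraries of the lowest level, si:ch211-209l18.2 was at most at 0.265 CPM. Whether these separate levels follow inherited chromosome segments was not tested. Among genes that did not pass, shisa9b, an auxiliary protein of glutamate receptors, had a log2 fold change of -0.97 ± 0.16 (edgeR adjusted p = 0.05), KLHL32 of -0.74 ± 0.13 and the phosphatase PTPRE (ENSDARG00000015891) of -0.50 ± 0.09.

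Clock genes in F2 males had a median of 0.23 over 45 genes (camera adjusted p = 5.64e-05; adjusted p = 0.803 with an estimated correlation), with 0 called over all genes, 14 higher and 3 lower over the list alone. Of these, dbpb stood at 0.74 ± 0.17, against -1.15 ± 0.25 in F1 males, and NR1D1, the repressor REV-ERB alpha, at 1.37 ± 0.31, neither called. Cytosolic ribosomal protein genes had a median of 0.23 over 75 genes (camera adjusted p = 5.21e-12; adjusted p = 0.835 with an estimated correlation) and potassium channel genes of -0.27 over 35 (0.0228; adjusted p = 0.835 with an estimated correlation, 0.158 without F2_M_PH 11 and 0.484 without F2_M_SCA 5). Markers of ciliated and choroid plexus cells had a median of 0.28 over 50 genes (0.000171; adjusted p = 0.803 with an estimated correlation), with 2 higher over the list alone. The photoreceptor and eye list had a median of -1.27 over 37 genes (0.00295; adjusted p = 0.835 with an estimated correlation, 0.511 without F2_M_SCA 3). Fitting all 48 libraries called 0 genes, and leaving out F2_M_PH 9 called 18.

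Averaged over both sexes of F2, 193 genes were called, 121 higher and 72 lower, and all 8 PH lay apart from all 8 SCA libraries in 60 of 17505 tested genes (0.34%, against 0.02% by chance), 43 of them called. These genes were chosen by the same rule after values were seen. The heat shock factor HSF2 rose by 0.73 ± 0.10 on the log2 scale, lgals9l1 by 1.05 ± 0.14, the synaptic vesicle protein sypb by 0.36 ± 0.06 and the axonemal gene TEKT1 by 1.91 ± 0.32. KLF9 was lower than in controls by 2.0 ± 0.30, EPX, a granulocyte peroxidase, by 2.07 ± 0.34, and the guidance receptor PLXNA1 (ENSDARG00000114823) by 0.60 ± 0.10. Of 45 clock genes, 10 were called higher and 2 lower over all genes, and 15 and 12 over the list alone. Those called higher included, picked outside the rule, NR1D1 (1.23 ± 0.21), ciarta (1.13 ± 0.19), CRY2 (0.69 ± 0.14) and dbpb (0.63 ± 0.12), the last of which had fallen in F1. Lane as a covariate left 55 calls, dropping both L2 females 21 and dropping both libraries that stood apart 67. In the fits with lane and without the L2 females, only the PH females of lane L3 set the level of their group. Of 16 libraries left out in turn, 14 moved the count by over 1.5 times, between 78 without F2_M_SCA 7 and 1192 without F2_F_SCA 9.

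**Figure D2:**
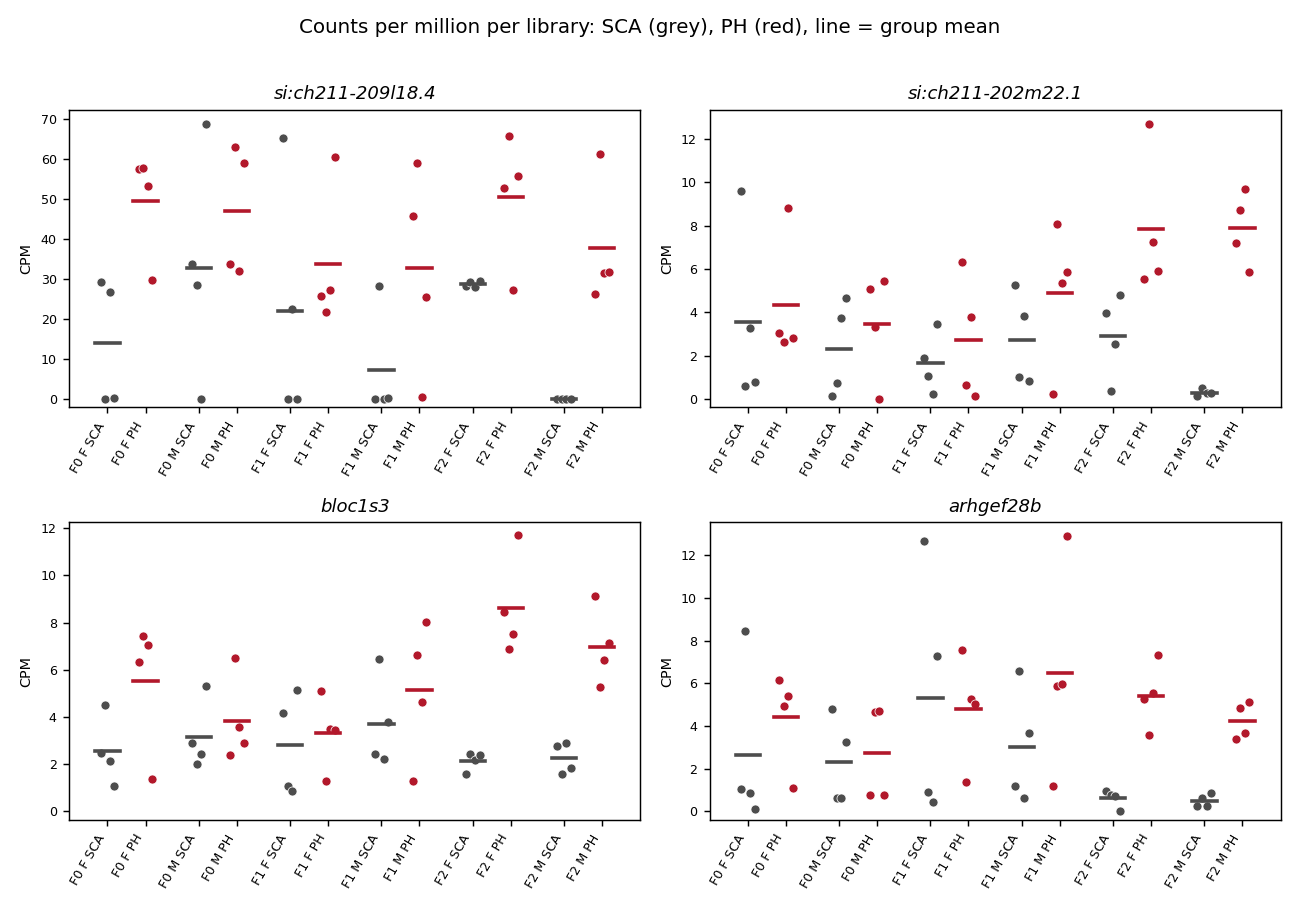
CPM (linear axis from 0) of si:ch211-209l18.4, si:ch211-202m22.1, bloc1s3 and arhgef28b in each of the 48 libraries, by generation, sex and arm; points are libraries, lines are group means, SCA is grey and PH red. The first transcript was at 0 in all 4 control F2 males and between 26.1 and 61.1 CPM in the 4 males of the permethrin lineage.

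Changes differed between generations in 34 genes in females and 40 in males by the joint edgeR test, and the genes named here were chosen after values were seen. In females, KLF9 (adjusted p = 0.0247) had a log2 fold change of 1.15 ± 0.72 in F0, -3.54 ± 0.55 in F1 and -2.64 ± 0.43 in F2. ERF (ENSDARG00000063417) had 0.07 ± 0.12, -0.92 ± 0.14 and -1.2 ± 0.20 in the same order (0.0247). In males, smu1b (0.00183) had 0.23 ± 0.16, -1.15 ± 0.21 and 0.38 ± 0.10, and dbpb (0.00214) had -0.07 ± 0.12, -1.15 ± 0.25 and 0.74 ± 0.17. Cry3b in males had 0.35 ± 0.20, 1.6 ± 0.24 and -0.37 ± 0.20 (0.00643). The female count moved between 0 without F0_F_PH 15 and 59 without F2_F_SCA 9, and the male count between 8 without F1_M_PH 6 and 121 without F1_M_PH 8.

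Genes called in both F1 and F2 females were SLC3A2, ERF and KLF9, all lower, against 0.00768 expected for independent lists. Over both sexes, 14 genes were lower in F1 and in F2 (0.285 expected), among them KLF9, ERF, SERTAD2, STK40, usp2b, csrnp1a and IRS2. Another 3, smu1b and dbpb among them, were lower in F1 and higher in F2 (0.46 expected), and histh1l1 was higher in both (0.335 expected). These expected counts treat genes as independent, so for genes that vary together they do not measure chance. Across genes, which are not independent replicates, fold changes of F1 and F2 females correlated at r = 0.32 (exact permutation p = 0.0473, adjusted p = 0.213 over 9 pairs) and those of F1 females and males at 0.247 (exact permutation p = 0.0269, adjusted p = 0.213). Female and male changes in F2 correlated at 0.398 (exact permutation p = 0.0898, adjusted p = 0.269). Founder females correlated at 0.121 with F1 females and 0.074 with F2 females, and founder males at 0.117 with F1 males and 0.24 with F2 males. F1 and F2 males correlated at 0.069, and founder females and males at 0.158. No pair passed after adjustment, with 0.000816 the smallest p that the assignments can give. Without F1_F_SCA 6 the F1 and F2 females passed (r = 0.385), and without F0_F_PH 9 the F0 and F2 females had r = -0.133.

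Between the sexes, edgeR called 877 genes in F0 (364 higher and 513 lower in females), 624 in F1 (356 and 268) and 20 in F2 (6 and 14), and 7 genes were called in all 3 generations in the same direction. DIO2, the deiodinase that activates thyroid hormone, stood at 16.7 ± 4.69 CPM in F0 females against 98.0 ± 10.5 in males (SD, n = 8 each), and its log2 difference was -2.55 ± 0.15, -1.87 ± 0.20 and -1.42 ± 0.13 over the generations. CA6, a carbonic anhydrase, had -1.40 ± 0.18, -0.88 ± 0.14 and -0.91 ± 0.16, atp1a3b, a neuronal sodium pump subunit, -1.02 ± 0.09, -0.65 ± 0.13 and -0.70 ± 0.11, and slc25a18, a mitochondrial glutamate carrier, -0.91 ± 0.09, -0.61 ± 0.11 and -0.74 ± 0.11. F13A1 (ENSDARG00000045453), a clotting factor subunit, was higher in females by 2.61 ± 0.60, 3.86 ± 0.42 and 3.82 ± 0.32. SUCLG1, a subunit of succinate-CoA ligase named outside the rule and chosen after values were seen, was also lower in females. Between F0 and F1, 68 genes lower in females were shared against 7.72 expected if genes were independent, and 19 higher against 7.38. In F0 the 4 SCA males ran on lane L2 and all other libraries on L4, so lane partly coincides with sex there. Counts moved with 1 library: without F1_M_PH 7, 158 genes were called in F1, and without F1_M_SCA 5, 1168; without F0_M_SCA 2 the F0 count was 533 and without F0_M_SCA 10 583, without F2_M_SCA 3 the F2 count was 10 and without F2_F_SCA 9 it was 73.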

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

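All tests of explanations in this part were chosen after the results had been seen; the counts over other splits of the samples were planned before.

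A first pattern is the clock genes among the calls of F1 and F2. A score of 45 clock genes, built from variation within groups and holding 28.8% of it, differed between lineage and control by -4.12 in F1 over both sexes (exact permutation p = 0.000408), and by 1.64 in F2 (p = 0.0645, exact permutation). With this score in the model, 0 of the 123 F1 calls were called again, but the score itself parts the arms: fold changes kept a median of 36.3% of their size in the 7 clock genes, from which the score is built (dbpb from -0.91 ± 0.17 to -0.32 ± 0.17, cry3a from 0.92 ± 0.13 to 0.43 ± 0.15), and of 72.3% in the other 116 (KLF9 from -3.26 ± 0.42 to -1.98 ± 0.55, adjusted p = 0.526, the highest of its alternatives from 7.47e-09), and standard errors grew 1.52 times (median), so the lost calls decide nothing and time of day at sampling cannot be told apart from an effect of the lineage in F1. In F2, 173 of 193 calls stayed past the threshold, and the 181 outside the clock list kept a median of 104.3% of their fold change. Those folds thus did not depend, in the median, on this 1 axis. Time of day is not decided for them, as the score holds 28.8% of the within-group variation and its F2 difference did not pass. The 12 clock genes kept 64% (9 called again, dbpb from 0.63 ± 0.12 to 0.39 ± 0.09) and stay open. The order of collection, with fish number standing for it, was not decided, as the mean correlation of score and number over 6 sets was 0.141 (permutation p = 0.369), a mean over opposite signs: r was 0.389, 0.706 and 0.834 in PH of F0, F1 and F2 (exact permutation p = 0.358, 0.0593 and 0.0124; adjusted p = 0.43, 0.178 and 0.0744; rho = 0.262, 0.762 and 0.595 with p = 0.536, 0.0368 and 0.132) and -0.096, -0.388 and -0.601 in SCA (p = 0.816, 0.351 and 0.111; adjusted p = 0.816, 0.43 and 0.222; rho = -0.19, -0.381 and -0.571 with p = 0.665, 0.36 and 0.151), and an effect of the permethrin lineage on the clock was not tested apart from sampling time.

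A second pattern is 27 genes called in F2 with a fold of over 4, si:ch211-209l18.4 among them. Of these, 13 spanned over 8-fold among the 8 F0 control fish in log2 CPM with a prior count of 2, which shrinks folds at low counts. The 95th percentile of 1000 random sets was 6. KLF9 was among the 13, at 4.61 to 40.1 CPM, with 9 of 16 control fish of F0 and F1 on its permethrin side. Variation between fish present before F2 may thus contribute to these 13. The other genes did not pass that span, which does not exclude such variation for them. Without the prior count, si:rp71-1h20.9 ran from 0.119 to 2.39 CPM and MATN4 from 13.2 to 106 in those control fish. In F0 and F1, 26.4% of gene and control fish pairs lay on the permethrin side of the F2 midpoint (95% bootstrap interval 20.4 to 32.2). Single genes ran from 0 of 16 control fish for si:dkey-287i17.5 to 9 of 16 for KLF9, with 8 of 16 for si:ch211-209l18.4. For the last 2 the permethrin side was not confined to that lineage, while an effect of the lineage stays open for the set. Chromosome segments inherited from different founders were looked for through neighbouring genes: 29 called genes had a called gene among the 5 nearest on each side, against a mean of 15.47 in random sets (permutation p = 0.00899). The test covers only the 145 of 193 genes (75.1%) that could be placed by name, on another assembly than the authors'. Inherited segments would give such an excess, but the excess does not show them. Founder ancestry and an effect of permethrin cannot be told apart here.

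The third pattern is ribosomal protein genes above and potassium channel genes below control in F2. The medians of these lists also moved in opposite directions between fish within groups of F0 and F1 (r = -0.69, permutation p = 0.00079, Spearman rho = -0.502, permutation p = 0.0121, adjusted p = 0.00132 over 5 relations, r = -0.548 without the 2 farthest libraries). An axis of tissue composition or RNA quality that is not tied to exposure could give this. The ribosomal median did not clearly follow the percent of mitochondrial counts there (r = -0.203, permutation p = 0.374, adjusted p = 0.468, r = -0.445 without the 2 farthest). RNA quality was not tested otherwise. Few genes taking more of the counts stays open as a cause: within groups, the ribosomal median correlated with the share of the 10 highest genes at r = 0.14 in F0 and F1 (permutation p = 0.566, Spearman rho = 0.099, permutation p = 0.659; r = -0.171 without the 2 farthest) but at r = 0.813 in F2 (permutation p = 0.00046, Spearman rho = 0.818, permutation p = 0.00074, adjusted p = 0.00115; r = 0.792 without the 2 farthest). In F2 the axis differed between arms by 0.587 (exact permutation p = 0.0633) and that share by 2.08 percentage points (17.22% in PH, 15.14% in SCA, exact permutation p = 0.0947). An effect of the lineage on these genes stays open and untested.

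Other ways of dividing the same samples were fitted to ask whether chance can be excluded for each count. Where the real count was 0, every split reaches it by construction and the splits decide nothing: 35 of 35 in F0 females (highest other 2) and in F0 males (1), and 100 of 100 for both sexes of F0 (3), the F0 sex difference (2) and the F1 sex difference (123, a split that exchanges the arms in males). Chance cannot be excluded for F1 females, where 2 of 35 splits reached the real 12 (highest other 15). A share of splits of at most 5%, not adjusted for the number of counts tested, was found for F1 males (1 of 35, real 19, highest other 2), F2 females (1 of 35, 24 and 3), F2 males (1 of 35, 3 and 2, a margin of 1 gene), F2 both sexes (1 of 100, 193 and 7), the sexes in F0 (1 of 100, 877 and 141) and in F1 (1 of 100, 624 and 248), and the generation test in males (1 of 100, 40 and 20). That share alone does not exclude chance: many counts were tested, and 1 of 35 is the smallest share that 35 splits can give. The F1 male count also fell to 0 without F1_M_PH 4. With lane as a covariate the F2 counts of females and of both sexes fell, in females to 0. That fit takes the PH female level from the 2 libraries on L3 alone, so the drop does not show an effect of lane. Such a share was also found for F1 both sexes (2 of 100, real 123, highest other 423), the F2 sex difference (4 of 100, 2 and 1641), the sexes in F2 (3 of 100, 20 and 887) and the generation test in females (4 of 100, 34 and 691), but these highest splits called several times the real count. What those splits divide was not tested. For counts of lists, chance cannot be excluded in any contrast: 7 of 35 splits in F0 females (real 16, highest other 18), 14 in F0 males (12 and 17), 4 in F1 females (14 and 19), 32 in F1 males (7 and 19), 11 in F2 females (13 and 19) and 23 in F2 males (10 and 18).

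The change in F2 differed between females and males for 2 genes by edgeR: si:ch211-209l18.4, with a difference of log2 fold changes of -10.34 (adjusted p = 0.000441), and si:ch211-209l18.2, with -5.57 (adjusted p = 0.0251). Neither size is reliable, because the 4 control males held 0 counts of the first and 1 of the second. Changes differed between generations for 34 genes in females and 40 in males.

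In 14 of 108 groups of 4 values, 1 library lay far from the others; chance gives about 1 in 20 such groups. Photoreceptor medians, in log2 against the generation mean, set apart F0_F_PH 10 at 0.2. Erythrocyte medians set apart F0_F_PH 16 at 0, F0_M_PH 12 at 0.73, F0_M_SCA 2 at 0.12, F2_F_PH 3 at -0.12 and F1_M_PH 4 at -0.07. Skeletal muscle medians set apart F2_M_PH 9 at -0.24 and F2_F_SCA 8 at 1.35. The number of genes detected was 22943 in F0_M_PH 12 and 23655 in F0_M_SCA 10. Pairs over no feature made up 63.84% in F2_M_PH 11. The 10 highest genes took 9.05% of counts in F1_F_PH 2 and 14.69% in F1_M_SCA 10, and mitochondrial genes 7.76% in F1_F_PH 2.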

How the results depend on the processing

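The fits without libraries that stood apart and with the clock score were chosen after seeing the data; the others were planned. Of gene counts under alternatives that leave out no single library, 82 stayed within 1.5 times and 72 moved; the cause was not tested unless stated. RLE size factors and a mean CPM of at least 1 moved no gene count by over 1.5 times.

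With DESeq2 the calls were 18, 10 and 57 in F0 females, males and both, with 1359 between the sexes; 150, 158 and 374 in F1, with 2 for the sex difference and 1481 between the sexes; and 551, 113 and 941 in F2, with 6 and 218. The generation tests gave 74 in females and 162 in males. With limma voom, F0 females gave 1 and the sexes 1555; F1 females 29, males 1 and the sexes 1430; F2 females 286, males 37, both 1700, the sex difference 0 and the sexes 132; the generation tests 86 and 83. A fit of all 48 libraries gave 32 in F0 females; 77, 74 and 293 in F1 and 975 between its sexes; 346, 0 and 938 in F2, 0 for the sex difference and 34 between the sexes. With 1 surrogate variable, F0 females gave 1 and the sexes 1953; F1 females 23 and the sexes 13; F2 males 14, both 62 and the sexes 109; the male generation test 80.

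Using only the 8 libraries of the contrast, which leaves fewer samples, calls were 1 in F0 females, 20 and 0 in F1 females and males, and 6 and 9 in F2. Without a filter on low counts, F2 males gave 5 and the female generation test 17. In F2 only 2 PH females ran on the other lane, so the fit with lane and the fit without them both rest on the remaining PH females. Lane as a covariate left 0 in F2 females, 55 in both, 1 for the sex difference and 7 between the sexes. Without the 2 PH females of the other lane these were 0, 21, 1 and 8. Without the 2 libraries that stand apart they were 12 in females, 67 in both and 1 for the sex difference. The clock axis score as a covariate gave 0, 0 and 0 in F1 females, males and both, 224 between the sexes, and 200, 7 and 965 in F2. In F0 males lane coincided with group, and in F1 no lane is named, so no fit with lane was made there.

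No paired analysis was possible outside F0 females, because elsewhere the arms of a sex share fewer than 2 replicate numbers. As a block, the 2 numbers shared in F0 females gave 60 calls in F0 females, with 1 residual degree of freedom; same-numbered fish correlated at 0.121 and 0.126, and with 2 pairs the numbers do not pair the samples.

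The correlation of fold changes turned negative for F0 with F1 females over the 2000 genes of highest mean CPM (-0.017), for F0 with F2 females by Spearman (-0.019), over those 2000 genes (-0.02) and without F0_F_PH 9 (-0.133) or F0_F_SCA 15 (-0.048), and for F1 with F2 males by Spearman (-0.059), over the 2000 genes (-0.269) and without F1_M_SCA 12 (-0.012). None of these correlations had passed. Lists past the threshold fell from 16, 12, 14, 7, 13 and 10 to 0 in all 6 contrasts with an estimated correlation and to 0 with fry.

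Leaving out 1 library in turn gave 0 to 1 calls in F0 females, males and both, 0 to 0 for their sex difference and 533 to 1076 between the sexes; 1 to 29, 0 to 46 and 60 to 158 in F1, 0 to 1 for the sex difference and 158 to 1168; 3 to 1251, 3 to 18 and 78 to 1192 in F2, 1 to 4 and 10 to 73. The generation tests gave 0 to 59 in females and 8 to 121 in males. Correlations ranged from 0.028 to 0.207 for F0 with F1 females, -0.133 to 0.203 for F0 with F2 females, 0.219 to 0.385 for F1 with F2 females, 0.045 to 0.216 for F0 with F1 males, 0.096 to 0.315 for F0 with F2 males, -0.012 to 0.154 for F1 with F2 males, and 0.017 to 0.221, 0.196 to 0.285 and 0.222 to 0.484 between the sexes of F0, F1 and F2. Lists numbered 16 to 20 and 8 to 13 in F0 females and males, 9 to 16 and 7 to 13 in F1, and 10 to 15 and 7 to 15 in F2. Of named genes called, 21 of 24 over both sexes of F1 and 20 of 21 of F2 were called in every such fit, against 0 of 10 and 0 of 14 in F1 females and males, 3 of 18 in F2 females and 3 of 3 in F2 males. Under every other alternative but the clock score, 21 of 24 over both sexes of F1 and 7 of 21 of F2 were called, against 7 of 10 and 0 of 14 in F1 females and males, 0 of 18 in F2 females and 0 of 3 in F2 males; with the score, none of the 24 was. The shallowest library, with 4802827 counts, was F1_F_PH 1, without which F1 females kept 1 call.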

Other observations

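Several gene groups fixed in advance have not been described yet in the contrasts given here. Voltage-gated sodium channel genes, the known targets of permethrin, had a median log2 fold change of 0.09 over 10 genes in F0 females (camera adjusted p = 0.952), with 0 called. Genes of xenobiotic metabolism had a median of -0.17 over 39 genes in F0 females (camera adjusted p = 0.00693; adjusted p = 0.345 with an estimated correlation), with 0 called over all genes and cyp2ad3 alone lower over the list alone. Genes of the cell cycle had a median of -0.18 over 42 genes in F0 females (camera adjusted p = 0.000657; adjusted p = 0.803 with an estimated correlation) and of -0.32 over 45 genes in F1 males (0.00255; adjusted p = 0.834 with an estimated correlation, 0.0635 without F1_M_PH 6), with 0 called in either.

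Radial glia and neurogenesis genes had a median of 0.09 over 44 genes in F2 females (camera adjusted p = 0.0319; adjusted p = 0.834 with an estimated correlation, 0.0728 without F2_F_PH 5, 0.0723 without F2_F_SCA 4 and 0.117 without F2_F_SCA 9). FABP7 (ENSDARG00000007697) was called higher, and 6 were higher over the list alone, among them her4.1, a Notch target, at 0.72 ± 0.21. Nuclear genes of oxidative phosphorylation had a median of 0.16 over 91 genes (1.85e-05; adjusted p = 0.834 with an estimated correlation), with 1 higher over the list alone. Liver plasma protein genes did not pass as a list in F2 females (camera adjusted p = 0.209), while 4 of 12 were higher over the list alone, including the yolk precursor vtg1 at 4.5 ± 1.31 (log2 fold change ± SE), with 0 called over all genes.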
